A study of Rattus norvegicus with 11 samples.

How the data were processed

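Total RNA of rat hippocampus was measured on 11 arrays, 6 from rats on a control diet and 5 from rats on a ketogenic diet, which is rich in fat and low in carbohydrate. The titles gave the diet and a replicate number for each sample. The labels do not say in so many words that each sample came from a separate animal, so p-values measure the spread between these samples. Replicate numbers are shared by both diets, and nothing in the labels says that they pair animals.

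The deposited values are linear probe set intensities, 1 column per array, for 15923 probe sets. The steps from scanner image to intensity are not given in the sources used here. The deposited intensities had a mean between 150.023 and 150.028 on each array after 2% of the values was trimmed at each end, as a global scaling of each array leaves it. Scanner files were not used here. For arrays, the number of arrays limits the precision.

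The main setting followed rules written before the data were examined. Medians of the log2 values spanned 0.24 between arrays, above the limit of 0.1, so quantile normalization between arrays was applied. Values below the 5th percentile of all values pooled, a signal of 4.99, were then set to it, and log2 values were used throughout. The 57 control probe sets were left out, and the 25% of probe sets with the lowest mean over all samples were not tested, which left 11899. The comparison, ketogenic minus control diet, was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. A probe set past it is described as called.

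Gene symbols came from the platform annotation and were updated through gene identifiers with a RefSeq gene table of the assembly GRCr8, from which no coordinates were taken. Of the 13101 probe sets in that annotation, 12789 had 1 gene symbol and 312 had several, while 2771 probe sets of the array were unnamed here. The gene identifiers of 12754 of the single-symbol probe sets were found in the gene table. A gene was represented by its tested probe set with the highest mean, among probe sets with 1 symbol, which gave 8397 genes. Probe sets with several symbols were not used to name genes, except that 5 globin probe sets are described as a family.

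Gene lists for pathways, cell types and brain regions, 36 in all, were written before the data were examined, and the 35 with at least 5 measured genes were tested with camera at a preset correlation of 0.01. Lists of energy metabolism were included in the knowledge of a published report on mitochondrial genes in hippocampus of rats on this diet, so they are not independent evidence of a direction. The named genes are the 12 called genes with the largest increase and the 12 with the largest decrease. Up to 3 members of each list with the smallest p were added, and a fixed set of genes. The fixed set covered ketone and fat metabolism, GABA synthesis, neuropeptides and stress, and held Bdnf. From the list members a selection was made after their values were seen, which favours called genes. Ppargc1a, of the fixed set, had no tested probe set, and 1 further item is not reported here. Some alternative settings were looked at before the final scripts were written, and the main setting stayed as fixed beforehand.

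Array measures were compared with exact two-sided permutation tests, in which 6 against 5 samples allow no p below 0.00216, with Benjamini-Hochberg adjustment over 7 measures. They were the ratios of 3 prime to 5 prime control probe sets for Gapdh and actin, the array median, the mean correlation with the other arrays, and scores on the first and second principal components. The mean level of bacterial spike-in probe sets, RNA added during labelling or hybridisation, was added after the data had been seen.

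The fit was tested on simulated data for this comparison, with 11899 probe sets drawn from the observed means and residual spreads. Of 100 probe sets changed by 0.5 on the log2 scale in either direction, 56 were called, and of 100 changed by 1, 89 were called. Among the 157 calls 12 had not been changed. A planted list shift of 0.2 was called, and 0 lists were called without one. Probe sets were drawn independently of each other, so the simulation cannot show how the list test acts where genes are correlated. In the measured data the estimated correlation was 0.115 for the cytosolic ribosome and 0.109 for ATP synthase. The planted shift is also larger than the medians of the 4 lists called higher, which were 0.11 to 0.17. The alternatives were other scalings, filters and floors, the replicate number as a block, array weights, other variance models, a threshold of 0.1, other list tests, the mean of all probe sets of a gene, and leaving out each sample in turn. Fits with the 3 prime to 5 prime ratios or the spike-in level as covariates were added after the data had been seen.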

Results

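Expression was compared in hippocampus between 6 samples from rats on a control diet and 5 from rats on a ketogenic diet, a diet that the labels describe as preventing epileptic seizures. Median deposited signals lay between 79.9 and 94.2 across the 11 arrays. Pearson correlations of log2 values were 0.959 to 0.974 between control arrays, 0.951 to 0.972 between ketogenic arrays and 0.933 to 0.964 between diets.

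The question of the design was which transcripts differ between the diets. The largest change was in globin transcripts. Hbb, the beta chain of haemoglobin, fell by 3.16 on the log2 scale (SE 0.13, adjusted p = 9.63e-10, limma), from 9.79 ± 0.24 (SD, n = 6) to 6.64 ± 0.29 (SD, n = 5), an 8.92-fold lower signal. Hba-a3, an alpha globin gene, was 2.16-fold lower (adjusted p = 0.00041). Camk2a, a calcium-dependent kinase abundant at synapses, rose by 1.34 (SE 0.23, adjusted p = 0.00395) from 9.31 ± 0.62 to 10.65 ± 0.20, and its 3 tested probe sets all had a positive sign. Among gene lists, 10 of 39 cytosolic ribosome genes, 10 of 27 proteasome genes, 10 of 81 genes of the mitochondrial ribosome and import and 5 of 16 ATP synthase genes rose, while 1, 1, 4 and 0 fell, and 4 of 11 choroid plexus markers fell. These 5 lists were called at a preset correlation and 0 of them with an estimated one (adjusted p = 0.317 to adjusted p = 0.613 with an estimated correlation). Over all 8397 genes 743 rose and 674 fell, and 16.5% of tested probe sets were called. In both directions together, the called share of the mitochondrial ribosome and import list was close to that over all.

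Of 11899 tested probe sets, 1961 were called, 1026 higher and 935 lower on the ketogenic diet, so that 52.3% of the calls were higher. On the values as deposited, the calls were 1076 higher and 1736 lower, or 38.3% higher. By gene, 743 were higher and 674 lower among 8397. Most changes were small, with a median absolute log2 fold change of 0.41 among the calls, and 55 calls reached 2-fold, 36 of them higher. In 832 probe sets, or 6.99%, the groups did not overlap, against 0.433% by chance. With the Gapdh and actin 3 prime to 5 prime ratios as covariates, an alternative added after the data had been seen, 6 probe sets were called, all of them for globins, and with the spike-in level as a covariate 63 were called. The count was 1170, 1251 and 1258 without control replicates 2, 3 and 5, and 1199, 842, 3165, 798 and 1244 without ketogenic replicates 1 to 5 in that order. Where a called probe set had another tested probe set for its gene, the signs were the same in 60.4% of 576 pairs (95% interval 56.3 to 64.4), against 50.3% of 290 random pairs. The interval takes the pairs as independent, although pairs with both members called counted in each direction. Some genes also gave several pairs, so the interval can be too narrow.

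Among the 12 genes with the largest increase, Wdr24, part of a complex upstream of the growth kinase mTORC1, was 4.37-fold higher (log2 fold change 2.13, SE 0.37, adjusted p = 0.00431). Inf2, an actin-regulating formin, was 3.97-fold higher (adjusted p = 0.00237), although control replicate 6 lay at 6.49 and ketogenic replicate 3 at 6.17. Cacnb1, a calcium channel subunit, was 3.26-fold higher, Pla2g12a, a phospholipase, 3.24-fold, and Ptprj, a receptor tyrosine phosphatase, 3.22-fold. Spint2, a protease inhibitor, was 2.89-fold higher, with control replicate 5 at 6.72 apart from the other controls. Hdgfl2 was 2.88-fold higher, Bckdhb, which takes part in breakdown of branched-chain amino acids, 2.87-fold, Ppie 2.62-fold, Ero1b, an oxidase of the endoplasmic reticulum, 2.54-fold, and Nkain1 2.34-fold. Control means of these genes other than Camk2a lay between 4.55 for Bckdhb and 5.56 for Spint2 on the log2 scale. Probe sets with a mean over all samples below 5.16 were not tested. Control means of Wdr24, Inf2, Cacnb1, Pla2g12a, Ptprj, Bckdhb, Ero1b and Nkain1 lay below that level. These genes passed the filter only through their ketogenic values.

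The genes with the largest decrease after Hbb were Scn4a, a sodium channel best known from skeletal muscle, 2.42-fold lower (log2 fold change -1.28, SE 0.29, adjusted p = 0.0126), and Igfbp2, which binds insulin-like growth factors, 2.31-fold lower (adjusted p = 0.0337). Ltbp2, a matrix protein, was 2.26-fold lower, Cp, which encodes the copper carrier ceruloplasmin, 2.17-fold, Crybb3, a lens crystallin, 2.15-fold, Nfatc4, a calcium-regulated transcription factor, 2.13-fold, and Wnt6 2.13-fold. Alas2, the first enzyme of haem synthesis in red cell precursors, was 2.11-fold lower (adjusted p = 0.0298). Olr1867, listed as an olfactory receptor, was at 6.50 ± 0.19 (SD, n = 6) on the control and 5.50 ± 0.48 (SD, n = 5) on the ketogenic diet, and Padi2, a peptidylarginine deiminase, was 1.98-fold lower (adjusted p = 0.00022). Ketogenic means of Scn4a, Ltbp2, Cp, Crybb3, Wnt6 and Alas2 lay between 4.49 and 5.03, below the testing level of 5.16. These genes passed the filter only through their control values.

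All 7 tested globin probe sets, of which 5 are shared between globin genes, were called lower, 6 of them by 2.16-fold to 13.1-fold. The seventh had a control mean of 7.68 and a ketogenic mean of 2.43, near the floor of 2.32, so that the size of its difference is set by the floor. Slc4a1, the anion exchanger of the red cell membrane, was lower by 1.56-fold (log2 fold change -0.64, adjusted p = 0.00468). Bpgm, an enzyme of red cell metabolism that other tissues also use, was higher by 0.34 on the log2 scale. The list of red blood cell markers had 4 measured genes, all of them called, 3 lower and 1 higher, and was too short to be tested.

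**Figure D1:**
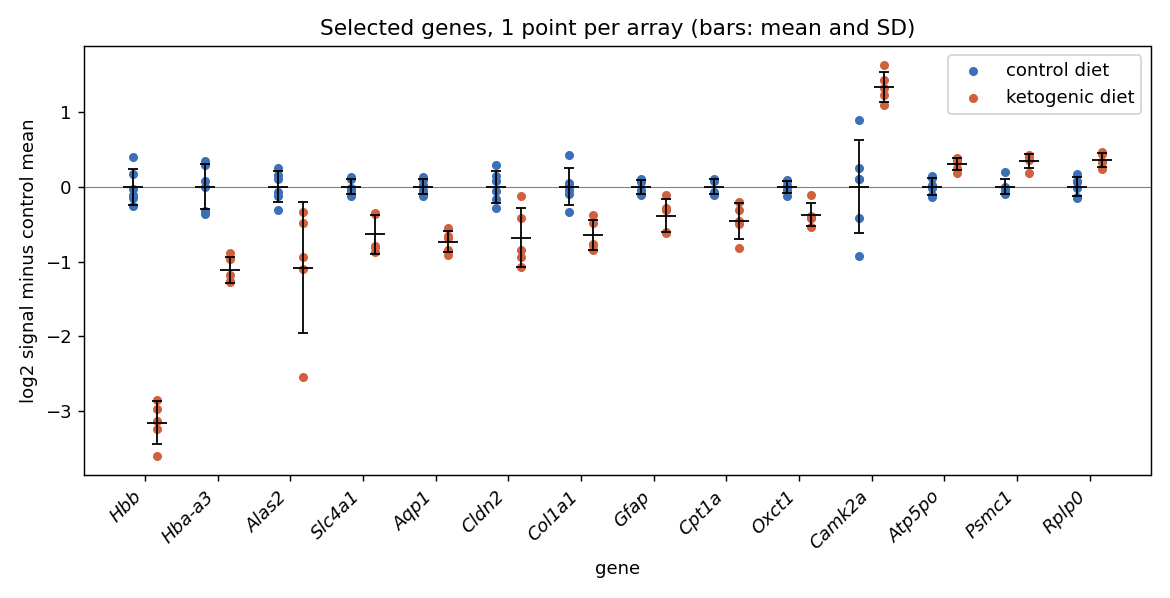
Log2 signal of selected genes minus the control mean of each gene, with 1 point per array and bars for the mean and SD of 6 control and 5 ketogenic arrays. Hbb fell by 3.16 on the ketogenic diet, while the differences of Atp5po, Psmc1 and Rplp0 are 0.30, 0.35 and 0.36.

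Of the 35 lists tested, 5 were called, 4 higher and 1 lower, and 0 were called with an estimated correlation between genes. With the 3 prime to 5 prime ratios as covariates 1 list was called, the cytosolic ribosome, with its median at 0.066, and the medians of the proteasome, the mitochondrial ribosome and import, and ATP synthase were 0.090, 0.047 and 0.063. With the spike-in level as a covariate 2 were called at the preset correlation, meninges and oligodendrocyte markers, both lower. Their estimated correlations without a covariate were 0.51 and 0.39, with camera adjusted p of 0.825 and 0.889. With the spike-in covariate the median was 0.11 for the cytosolic ribosome and 0.21 for the proteasome. It was 0.13 for the mitochondrial ribosome and import and 0.13 for ATP synthase. The cytosolic ribosome list had 10 members that rose and 1 that fell of 39 measured, and 13 and 1 adjusted over the list alone. Its median log2 fold change was 0.12 (camera adjusted p = 0.000891, and adjusted p = 0.426 with an estimated correlation). The median was 0.24 on the values as deposited and 0.27 centred on the 75th percentile. Rplp0 rose by 0.36 (SE 0.07), Rps23 by 0.33 (SE 0.08) and Rpl4 by 0.28 (SE 0.07). Of 27 measured proteasome genes, whose products degrade tagged proteins, 10 rose and 1 fell, and 13 and 2 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.00366, and adjusted p = 0.317 with an estimated correlation). Psmc5 rose by 0.39, Psmd7 by 0.36 and Psmc1 by 0.35, with control replicate 6 high and ketogenic replicate 3 low in their groups for Psmc1.

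Mitochondrial genes moved in part, in lists that were chosen knowing of a published report and are not independent evidence of a direction. The list of the mitochondrial ribosome and import had 10 members that rose and 4 that fell of 81, also adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.00692, and adjusted p = 0.317 with an estimated correlation). Mrpl22 rose by 0.66 (SE 0.15) and Mrpl38 by 0.48 (SE 0.10), while Mrpl40 was at -0.47 (SE 0.10), and the other probe set of Mrpl40 had the opposite sign. Of 16 ATP synthase genes 5 rose and 0 fell, and 6 and 0 adjusted over the list alone, with a median of 0.11 (camera adjusted p = 0.0452, and adjusted p = 0.613 with an estimated correlation). That median was 0.22 on the values as deposited and 0.26 centred on the 75th percentile. The mean of the ATP synthase members, relative to the control mean, overlapped between diets. It was -0.078 to 0.098 on control arrays and 0.074 to 0.141 on ketogenic arrays. For the cytosolic ribosome, the proteasome and the mitochondrial ribosome and import such means did not overlap. The ATP synthase call held in 5 of 11 fits with 1 array left out, and its adjusted p was 0.113, 0.0645 and 0.0510 without control replicates 3, 5 and 6, and 0.0588, 0.0986 and 0.0561 without ketogenic replicates 2, 3 and 4. Atp5f1d rose by 0.32, Atp5po by 0.30 and Atp5pd by 0.20. In complex I of the respiratory chain, 7 members rose and 2 fell of 35, and 8 and 2 adjusted over the list alone, and the list was not called (adjusted p = 0.285). Ndufa5 rose by 0.44, while Ndufv3 was at -0.57 and Ndufb1 at -0.54. Complexes II to IV had 4 members higher and 1 lower of 22 (adjusted p = 0.811), with Uqcrfs1 at 0.25 and Sdhc at -0.28. The citrate cycle list had 4 higher and 2 lower of 18 (adjusted p = 0.811), with Idh2 at 0.29 and Sucla2 at -0.16, and both lists had the same counts adjusted over the list alone. The calls of these 3 lists depended on the scaling, since on the values as deposited complex I, complexes II to IV and the citrate cycle were called higher, with medians of 0.13, 0.16 and 0.060, and centred on the 75th percentile they were also called, with medians of 0.16, 0.19 and 0.094.

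Genes of ketone and fat metabolism were not called as a group. Oxct1, the enzyme that activates ketone bodies for use in tissues, fell by 0.37 (SE 0.07, adjusted p = 0.00624) and was the 1 called member of 7 in the ketone list (list adjusted p = 0.509). That list had a median of -0.10, with 2 of its 7 members positive, and adjusted p = 0.0530 with fry, another list test. Bdh1, which interconverts the main ketone bodies, had a log2 fold change of 0.23 (SE 0.19, adjusted p = 0.425), and the monocarboxylate transporter gene Slc16a1 one of -0.25 (adjusted p = 0.0833), and was called on the values as deposited (-0.29) and without control replicate 1 (-0.32), with adjusted p from 0.0297 to 0.921 over its alternatives. Cpt1a, which admits fatty acids to mitochondria, fell by 0.46 (SE 0.10, adjusted p = 0.0116), and Eci1, an enzyme of fatty acid oxidation, rose by 0.61 (SE 0.12, adjusted p = 0.00624), with ketogenic replicate 1 at 6.41 below the other 4. The fatty acid oxidation list had 5 members higher and 4 lower of 37 (adjusted p = 0.811). Pdk4, a brake on glucose oxidation, had a log2 fold change of -0.15 (adjusted p = 0.319), and 0 of 18 glycolysis genes were called (list adjusted p = 0.811), while the list was called higher on the values as deposited and when centred on the 75th percentile. The counts of these lists adjusted over the list alone did not differ from those over all genes.

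Markers of choroid plexus, the tissue that makes cerebrospinal fluid next to the hippocampus, had 4 members that fell and 0 that rose of 11, and 5 and 0 adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.00859, and adjusted p = 0.317 with an estimated correlation). Aqp1, a water channel, fell by 0.73 (SE 0.08, adjusted p = 0.00022), Cldn2, a junction protein, by 0.68, and Folr1, a folate receptor, by 0.46. The list median was -0.26 with the 3 prime to 5 prime covariates (adjusted p = 0.0577) and -0.40 with the spike-in covariate (adjusted p = 0.0679). The median was -0.53 without control replicate 3 and -0.57 without ketogenic replicate 1. The mean of the choroid plexus members, relative to the control mean, overlapped between diets. It was -0.27 to 0.32 on control arrays and -0.64 to -0.15 on ketogenic arrays. Meninges and fibroblast markers had a median of -0.40 but 1 called member of 12 (list adjusted p = 0.0767), Col1a1 at -0.65, and were called lower under both other scalings, with array weights (adjusted p = 0.0425) and without control replicate 2, control replicate 6 or ketogenic replicate 1 (adjusted p = 0.0119, 0.0363 and 0.00449). Vascular markers had 1 called member of 12 (median -0.15, list adjusted p = 0.515), Slco1a4 at -0.47, with 1 called adjusted over the list alone in either list.

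Among other genes fixed beforehand, Gad1 had a log2 fold change of 0.10 (adjusted p = 0.353) and Gad2 one of -0.09 (adjusted p = 0.599). Bdnf had one of 0.04 (adjusted p = 0.818) and Npy one of -0.28 (adjusted p = 0.177). Npy was called lower without ketogenic replicate 3 (-0.40), where that array lay at 9.16, and with array weights (-0.37), with adjusted p from 0.0247 to 0.932 over its alternatives. Gad1 was called higher on the values as deposited (0.23) and centred on the 75th percentile (0.27), with adjusted p from 0.0224 to 0.904 over its alternatives. In the main setting the other probe set of Gad1 had the opposite sign. Fkbp5, a glucocorticoid-responsive gene, had a log2 fold change of 0.27 (adjusted p = 0.149). In the GABA list 2 of 17 members were lower, Gabra6 at -0.65 and Gabrg1 at -0.38 (list adjusted p = 0.811), and 1 adjusted over the list alone.

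**Figure D2:**
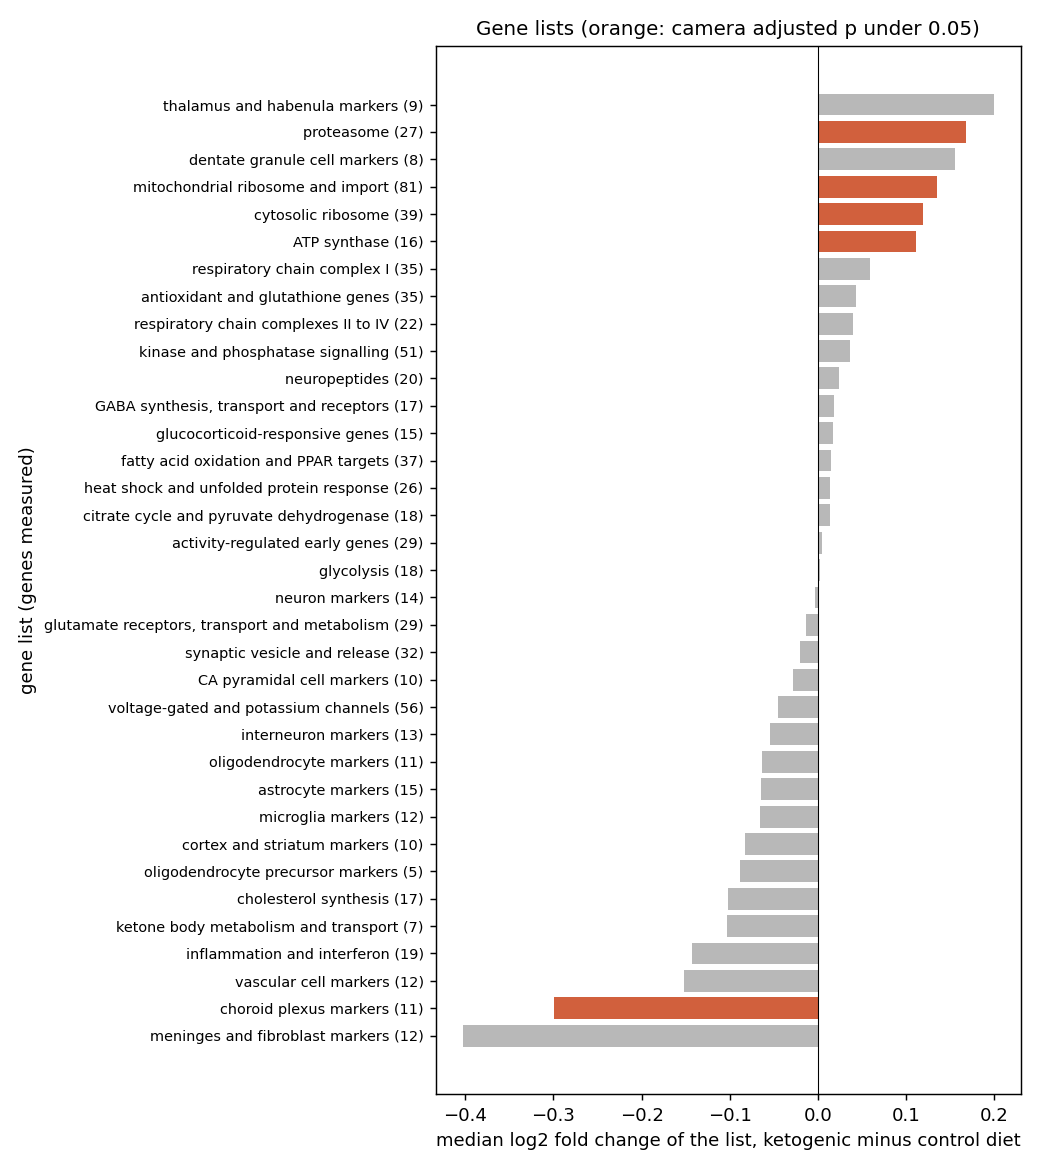
Median log2 fold change, ketogenic minus control diet, of each of the 35 gene lists tested, with the number of measured genes in parentheses and camera calls in orange. The proteasome list has a median of 0.17 and the choroid plexus list one of -0.30, and 0 lists were called with an estimated correlation.

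The arrays also differed between diets in measures of whole arrays. The log2 ratio of 3 prime to 5 prime probe sets, which rises as RNA degrades, was higher on the ketogenic diet for Gapdh by 0.20 (exact permutation test, p = 0.00649, adjusted 0.00909) and for actin by 0.19 (exact p = 0.00216, the smallest possible, adjusted 0.00505). The median log2 signal as deposited differed by -0.14 (exact p = 0.00216, adjusted 0.00505), and the mean correlation with the other arrays by -0.00444 (exact p = 0.0238, adjusted 0.0278). That correlation was taken over the tested probe sets, and a ketogenic array had fewer partners of its own diet than a control array. It is therefore not independent of the gene differences and does not by itself show poorer ketogenic arrays. No label gave a scan date or batch, so batch and diet cannot be told apart.

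The first principal component held 34.5% of the variance and separated the diets (exact p = 0.00216, adjusted 0.00505), and the second, with 10.4%, did not (exact p = 0.541). Ketogenic replicate 3 scored -2.82 on the first component, against 18.7 to 25.8 for the other ketogenic arrays and -17.3 to -10.6 for the controls. Its mean correlation was 0.961 with the control arrays and 0.952 with the other ketogenic arrays.

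**Figure D3:**
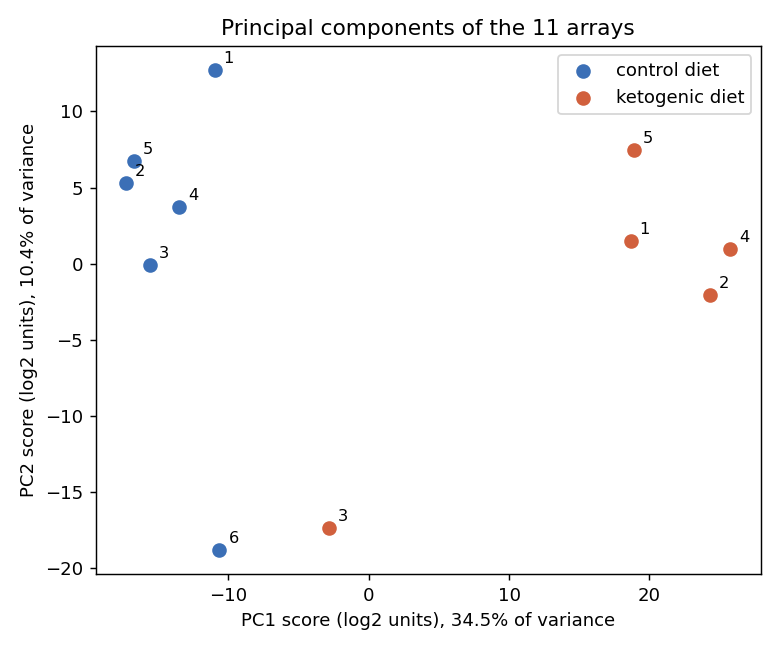
Scores of the 11 arrays on the first and second principal components of the log2 values of tested probe sets, labelled by replicate number, with control diet in blue and ketogenic diet in orange. Ketogenic replicate 3 lies at -2.82 on the first component, between the control arrays and the other ketogenic arrays.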

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

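The tests on globins and on ketogenic replicate 3 in this part were chosen after those results had been seen. Among 304 groups of values tested for an array far from the rest, 21 had one, where chance gives about 1 in 20 groups, or 15.2. In 11 of the 21 it was ketogenic replicate 3.

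On the first principal component ketogenic replicate 3 stood apart at -2.82, and it carried 0.353 of the difference between the diets where the other ketogenic arrays carried 0.884 to 1.10. Control arrays carried 0.0215 to 0.301, with control replicate 6 the highest, so 0.353 is little above a control array. Each share rests on the probe sets called without that array. They numbered 806 to 1236 for the other ketogenic arrays and 3166 for ketogenic replicate 3. A control sample taken like the other controls but under a ketogenic label is argued against by Hbb. It was at 6.95 on this array and at 9.53 or more on every control array. RNA of such controls mixed in at the proportion of its diet share would give Hbb a level of 9.25, and the array lay at -2.30 from it. If low Hbb came from the way the tissue was taken, Hbb could not decide on the diet of this sample or of RNA mixed into it. Its Gapdh 3 prime to 5 prime ratio of 0.127 was the lowest of the ketogenic arrays and below that of control replicate 6 at 0.148, and its actin ratio was 0.770, in a ketogenic range of 0.755 to 0.985. RNA quality, a separate batch and a weaker response of this sample to the diet, stay open, since no label ties arrays to batches, although its title ends differently from the others.

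Hbb and the other globin probe sets were lower on every ketogenic array. Scaling of the arrays is argued against by the values as deposited, on which Hbb had a log2 fold change of -3.17. Loss of all blood and vessel cells is argued against by the vascular markers, with a median of -0.15 (quartiles -0.27 and 0.05). Fewer red blood cells in the tissue goes with the mean log2 fold change of -0.86 for Alas2 (-1.08) and Slc4a1 (-0.64), although Bpgm was higher. Alas2 and Slc4a1 both fell less than Hbb, and Alas2 passed the filter only through its control values. Red cell content was not measured by other means, and the diet and the way the tissue was taken both stay open and untested.

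The same array also stood apart among ketogenic arrays in named genes, with Inf2 at 6.17, Klf2 at 6.29, Psmc1 at 8.59 and Socs3 at 5.02 below the others, and Mt2A at 9.61 and Sod3 at 7.36 above them. Its mean over list members, relative to the mean of all arrays, was 0.14 for interneuron markers, 0.15 for oligodendrocyte markers and -0.11 for thalamus and habenula markers.

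Other ketogenic arrays apart from their group were replicate 4 for Bdh1 at 6.55, replicate 1 for Eci1 at 6.41 and replicate 2 for the ketone list at -0.12. Among control arrays, replicate 6 stood apart for Inf2 at 6.49, Grik4 at 4.47 and Psmc1 at 8.60. Control replicate 5 stood apart for Spint2 at 6.72 and Sqle at 6.60, control replicate 2 for Uchl1 at 10.67 and control replicate 1 for the vascular list at -0.18.

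Outside the genes tested, the bacterial spike-in probe sets had higher deposited values on the ketogenic arrays. The difference was 0.39 on the log2 scale or 1.31-fold (exact permutation test, p = 0.00433, adjusted 0.00758). The deposited arrays share a common trimmed mean, so this level is relative to the sample signal of each array. A weaker sample signal could raise it too.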

How the results depend on the processing

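Fits with covariates, and the share of higher calls under other variance models, were added after the data had been seen. A sign change is counted where the value was called in the main or the alternative setting. The cause was not tested for any change below unless stated. The count of 1961 calls became 3137 with array weights, 412 with an unequal-variance test for each probe set, 3071 at a threshold of 0.1, 63 with the spike-in covariate and 6 with the 3 prime to 5 prime covariates, and 798 to 3165 when 1 array was left out. The share of 52.3% higher became 38.3% on values as deposited, 49.4% centred on the 75th percentile, 55.2% with no filter, 57.8% with the unequal-variance test, 41.3% with the spike-in covariate and 0% with the 3 prime to 5 prime covariates, and 50.1% to 53.8% when 1 array was left out. The 5 lists called became 13 on values as deposited and 13 when centred on the 75th percentile, 2 with the lowest 50% of probe sets left out, 0 with an estimated correlation, 1 with the 3 prime to 5 prime covariates and 2 with the spike-in covariate, and 4 to 6 when 1 array was left out. Under both scalings the added lists were complex I, complexes II to IV, citrate cycle, kinase signalling, glycolysis and neuron markers, higher, and inflammation and meninges, lower. Glycolysis and neuron lists turned to called higher, with medians of 0.091 and 0.14 as deposited and 0.12 and 0.17 centred. Over all alternatives the medians of the called lists ran from 0.066 to 0.27 for the cytosolic ribosome, 0.090 to 0.24 for the proteasome, 0.047 to 0.15 for the mitochondrial ribosome and import, 0.063 to 0.26 for ATP synthase and -0.57 to -0.26 for the choroid plexus.

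Of 2355 recomputed values of 109 named genes, 1910 kept side and sign, 425 lost and 7 gained the call, and 13 changed sign. Of the 101 called genes, Hbb alone kept its call in every alternative that gave it a value. Besides those that changed sign, the call was lost by 89 with the 3 prime to 5 prime covariates and by 93 with the spike-in covariate, and, with 1 array left out, by up to 31, without ketogenic replicate 2 and without ketogenic replicate 4. With the 3 prime to 5 prime covariates the values were -0.061 for Ero1b, -0.025 for Nkain1, 0.43 for Ltbp2, 0.14 for Cp, 0.14 for Gabrg1, 0.26 for Grm8, -0.054 for Rps23, 0.010 for Ifit1, 0.022 for Ugt8, -0.0803 for Ctss and -0.20 for Fibcd1. Socs3 was at 0.056 with the spike-in covariate, and Klf2 at -0.00745 as the mean of its probe sets. The replicate numbers gave no pairing, with correlations of 0.00888 to 0.0771 between samples of the same number, 0 of 5 over 0.1, and 2 of 5 ketogenic samples closest to the control of their own number. With the replicate block 1815 probe sets and 7 lists were called, the added lists being meninges (median -0.48, adjusted p = 0.0346) and oligodendrocyte markers (-0.11, adjusted p = 0.0300), and Npy was called at -0.35 (adjusted p = 0.0461). Low signals near the floor limit the fold of dim probe sets.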

Other observations

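The test on other probe sets of a gene was chosen after part of its values had been seen, and the covariate fits were added after the data had been seen, with their bounds set before they were run. Some groups of genes had called members in both directions. In cholesterol synthesis Msmo1 fell by 0.43 (SE 0.07) and Fdft1 by 0.40 (SE 0.07), while Sqle rose by 0.37 (SE 0.10), and 1 member was higher and 2 lower of 17 (list adjusted p = 0.432, and 0.0383 with fry). Glial genes were lower where called in the astrocyte list, Gfap at -0.39 and Aqp4 at -0.33 (2 of 15, list adjusted p = 0.598), and in the oligodendrocyte list, Mag at -0.52 and Ugt8 at -0.42 (2 of 11, list adjusted p = 0.317, and 5.11e-05 with the spike-in covariate). Microglial genes differed in sign, with Aif1 at -0.57, Csf1r at -0.30 and Ctss at 0.39, and the other probe set of Aif1 had the opposite sign. In the interferon and inflammation list Socs3, Ifit1 and Irf7 were at -0.67, -0.48 and -0.44, and 3 of 19 were lower and 0 higher (list adjusted p = 0.118). That list was called lower on the values as deposited (median -0.26), centred on the 75th percentile (-0.23) and with fry (adjusted p = 0.000348), which does not compare it with other genes, and its mean relative to the control mean was -0.21 to -0.13 on ketogenic arrays and -0.037 to 0.057 on control arrays.

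Genes of neuronal signalling were called in both directions too. Synaptic vesicle genes had 5 members higher and 5 lower of 32 (list adjusted p = 0.958), with Syt5 at 0.31 and Cplx2 at -0.68. Ion channel genes had 4 higher and 6 lower of 56 (list adjusted p = 0.515), with Scn1a at 0.37 and Kcnj9 at -0.64. Among CA pyramidal markers Grik4 was at 1.04, Fibcd1 at 0.47 and Bok at -0.33 (list adjusted p = 0.913). The list of heat shock and unfolded protein response genes included Ddit3 at 0.43, Pdia6 at 0.29 and Chac1 at -0.37, with 4 higher and 3 lower of 26 (list adjusted p = 0.811). The other lists not called had adjusted p up to 0.959. Adjusted over the list alone, higher and lower counts were 2 and 3 for cholesterol synthesis, 0 and 2 for astrocytes, 0 and 3 for oligodendrocytes, 2 and 2 for microglia, 0 and 3 for the inflammation list, 6 and 5 for vesicle genes, 4 and 7 for channels, 2 and 1 for CA markers and 6 and 4 for heat shock and unfolded protein response genes. The median was above 0 while the test leaned to lower for glycolysis, antioxidant, GABA and early genes, and the reverse held for CA pyramidal markers. For neuron markers the median was below 0 and the mean above it.

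Many probe sets were called with small fold changes. Of 100 splits of the 11 arrays, 1, the real one, called 1961 probe sets or more, and the highest of the others called 22. A chance split is thus argued against as the source of the count, although 100 splits allow no share below 1 in 100. The other splits mix the diets, so the difference between diets widens their spread within groups and can hold their calls low. For lists, 2 of 100 splits called as many as the real 5, and the highest other called 6, a share under 0.05, and that other split was the split by diet with control replicate 2 moved to the ketogenic side. Hybridisation strength as read by the spike-ins, whose level is relative to the sample signal, stays open and cannot be told apart from diet. The spike-in level was 8.53 to 8.86 on control arrays and 8.92 to 9.23 on ketogenic arrays, without overlap. With it as a covariate the called fold changes kept a slope of 1.16 (0.944 to 1.25 with 1 array left out). The median SE rose from 0.11 to 0.21, which ended most calls. RNA quality as read by the 3 prime to 5 prime ratios stays open and cannot be told apart from diet, with a slope of 0.70 (0.668 to 0.901 with 1 array left out), a median absolute log2 fold change of 0.25 in place of 0.41 and a median SE of 0.19. Responses of single probe sets also stay open, since other probe sets of a gene had the sign of a called one in 60.4% of pairs. The share was 60.3% and 60.6% for second probe sets above and below the median level, and 27 of 43 pairs, or 62.8%, where both were called.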
